A study of Polypedilum vanderplanki with 72 samples.

How the data were processed

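PolyA RNA of Pv11 cells was sequenced in 72 libraries, 3 for each of 24 groups, per the labels. The labels' protocols name an RNA Plus kit for extraction, poly(A) selection with magnetic beads and the NEBNext Ultra II kit for library preparation. The authors deposited a single table of counts, whole numbers of reads per annotated transcript that are not normalized. Per the submitters' processing notes, reads were checked with FastQC 0.11.9, trimmed with Trimmomatic 0.39, aligned with HISAT2 2.2.1 and counted with HTSeq 2.0.9. The notes and labels name neither the genome build nor the annotation, and no strand setting, so reads of overlapping or antisense genes cannot be told apart.

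The table lists 65235 transcripts of 17156 genes and 5 special rows, such as reads without a feature, which were left out of library sizes and tests. Reads without a feature came to between 38.3% and 46.5% of the sum of gene counts and reads without a feature in a library. A read appears to have been counted in every transcript of a gene that it overlaps. The reason is that all transcripts sum to between 18.5 and 26.1 times the gene counts described next, though transcripts of a gene can differ, as those of g3611 below do. The main measure was therefore 1 transcript per gene, that with the highest total over all libraries. Gene counts per library ran from 3043636 to 8808472. At this depth the floor of 3 counts over the 3 libraries of a group lies between 0.0978 and 0.300 CPM for the groups where it was needed. Libraries of a group spread more than counting error alone: over 72 pairs of libraries of the same group, the variance over that of counting error had a median of 3.14, with 2.21 the lowest and 15.3 the highest. The 7 values above 9 were all at R24.

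Genes could not be named. None of the IDs matched a locus tag, accession or symbol of the reference table of 17863 loci, and the deposited table pairs no ID with a name. The 27 gene lists and 9 signature lists fixed before the data were examined, heat shock proteins and late embryogenesis abundant proteins among them, were therefore void, as were the alternatives planned for them with camera and with another pseudocount. The rule for named genes, fixed before the data were examined, allowed in that case 2 IDs that rose and 2 that fell per comparison. These were the largest log2 changes among genes past an adjusted p of 0.05 whose libraries did not overlap between the groups and whose mean was 5 CPM or more in at least 1 of them. For tests over isoforms they were the smallest p values. A gene named by the rule in 1 comparison is also given in others. Fewer than these IDs are given for most comparisons, to keep the text short.

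Counts were analysed with edgeR 4.0.16 and limma 3.58.1 in R 4.3.3. Genes with low counts were removed by filterByExpr with the groups, libraries were scaled by TMM, and the quasi-likelihood test was used with Benjamini-Hochberg adjusted p under 0.05 as the threshold. All groups of a treatment shared a fit, with 27 libraries and 8255 genes at T48, 18 libraries and 8929 genes at R24, and 27 libraries and 8264 genes at HS6h. Contrasts across treatments came from a fit of all 72 libraries with 9231 genes. No covariate was used, because the labels give no batch. P-values measure the spread between these 3 libraries per group, which may be technical, since the labels do not say whether libraries come from separate cultures.

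A gene counted as back toward WT in a line when it differed between KO and WT and differed between the line and KO in the opposite direction, whether or not it passed WT. It counted as past WT when the line also differed from WT in that direction. Sets of KO-affected genes took those at least 2-fold changed in KO against WT. A set's score is its mean of log2(CPM + 0.5) minus that of WT, and sets were tested with fry of limma, whose p-value tests whether the genes of a set move, on balance, in a single direction. Adjusted p values of sets run over all 160 set tests. For overlaps, unchanged groups were simulated 20 times at the fitted means of the shared libraries. Such draws leave out the chance error of those libraries, so they cannot measure what sharing adds. The sets, the scores, the tests on them, the split of heat-induced genes and the simulations were chosen after the data were examined. The comparisons and their tests were fixed before.

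Folds against a group with 0 counts are lower bounds against a floor of 3 counts over the group. Groups with 1 to 3 counts are given as ratios with exact Poisson 95% intervals. The edgeR steps were checked on simulated counts with known changes. For KO against WT at T48 they recovered 55.2% of genes changed 1.5-fold, 97.0% of those changed 2-fold and 98.5% of those changed 4-fold, with 4.57% of calls false. Over 7 simulated comparisons the share of false calls lay between 1.71% and 6.63%. It exceeded the threshold of 0.05 for V1 against KO at T48 (6.11%) and for differences among the isoforms at HS6h (6.52%) and R24 (6.63%).

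Alternatives planned before the data were examined were RLE size factors, DESeq2 1.42.0, no filter on low counts, fits of only the groups compared, a fold threshold of 2 and leaving out each library in turn. The sum over all transcripts of a gene, and keeping 1 of each pair of genes with nearly identical counts (56 pairs, 82 genes), were added later. Genes that share reads with a near-identical copy could not be resolved and remain uncertain. The HSF1 gene was not analysed here for want of its ID.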

Results

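Pv11 is a cultured cell line from the sleeping chironomid Polypedilum vanderplanki, a midge whose larvae survive almost complete drying. Pv11 cells survive drying when they are first held in trehalose, the disaccharide that these larvae accumulate. HSF1, heat shock factor 1, is the transcription factor that switches on heat shock genes. The series measured polyA RNA in 72 libraries of wild-type cells (WT), cells without HSF1 (KO) and 7 lines that express a single HSF1 form in the KO background. Of these lines, 5 carry Pv isoforms (V1, V2, V3, V4 and V5-6) and 2 carry the Drosophila forms HSF1a (Dma) and HSF1b (Dmb). Each of the 24 groups has 3 libraries. All 9 genotypes were measured after 48 h in 600 mM trehalose (T48) and after 6 h of heat shock (HS6h). WT and the 5 Pv isoform lines were also measured 24 h after rehydration, which followed 11 days of desiccation (R24). No untreated cells are among the groups.

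The gene counts per library ran from 3043636 to 5091075 at T48, from 4951847 to 8808472 at R24 and from 4374617 to 7199241 at HS6h. The rows carry gene models numbered from the annotation, and none of the 17156 gene IDs is paired with a gene name. The level of HSF1, which would check the KO labels, could therefore not be read, and genes are given by ID. Heat-induced genes, in what follows, are genes that were higher in WT after heat shock than at T48. The labels do not say whether heat-shocked cells had trehalose, so without untreated cells a rise by heat could not be separated from an effect of trehalose at T48 or of batch.

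What HSF1 was needed for after heat shock was asked by comparing KO with WT at HS6h. Without HSF1 the heat-induced transcripts g238 and g241 were almost absent, while most other heat-induced genes were not lower. The transcript g238 had 2555 ± 167 CPM (SD, n = 3) in WT and 0.286 ± 0.0775 in KO, a log2 difference of -12.98 (SE 0.33). CPM throughout are counts scaled to library totals that were adjusted by the TMM factors of all 72 libraries. The transcript g241 had 1228 ± 116 CPM in WT, and KO held 1 count of it in all 3 libraries. That is a ratio of 16779, with an exact Poisson 95% interval of 3012 to 662741. The largest rises in KO were g11936, at 100.7 ± 6.10 CPM against 0.247 ± 0.214 in WT (log2 8.51, SE 0.38), and g12707, at 8.04 ± 0.814 CPM against 0 in WT, at least 44.3-fold higher. Intervals and floors here and elsewhere cover counting error only. The adjusted p values of edgeR's quasi-likelihood test were 2.81e-17 for g238, 1.57e-16 for g241, 1.32e-15 for g11936 and 4.75e-15 for g12707. All 3 KO libraries lay on the same side of all 3 WT libraries, which the rule for named genes required.

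Over the 8264 genes tested at HS6h, 2328 differed between KO and WT, 1087 higher and 1241 lower in KO. Large differences leaned toward loss: 353 genes were at least 2-fold lower and 211 at least 2-fold higher.

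**Figure D1:**
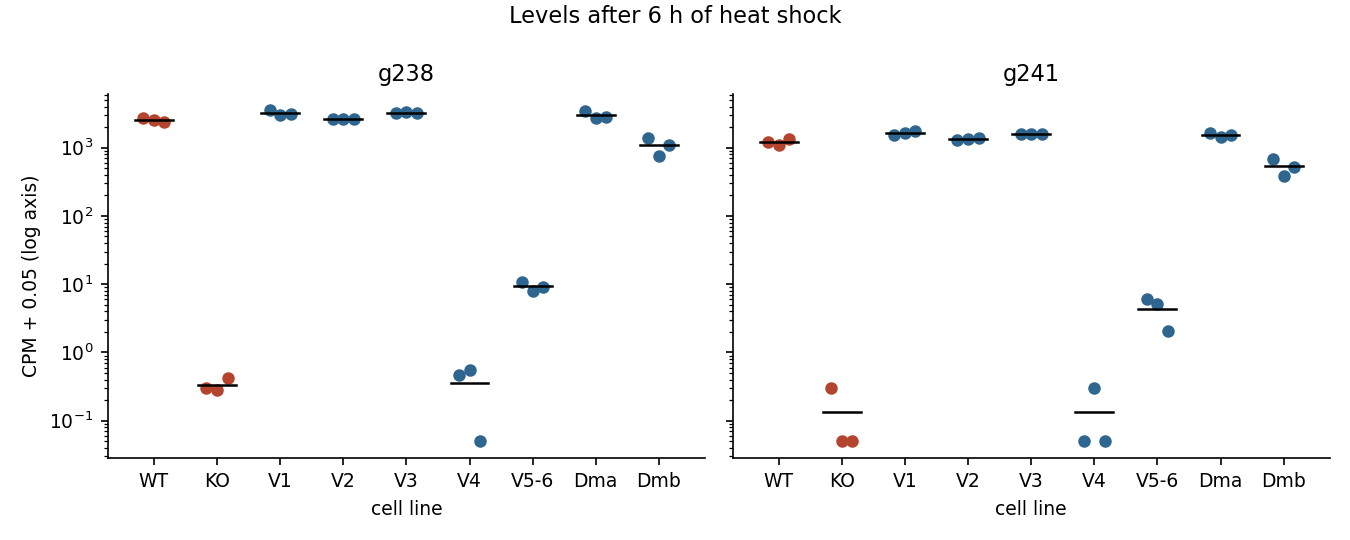
CPM of g238 and g241 after 6 h of heat shock, with an offset of 0.05 on a log axis, in each library (points) and as the group mean (lines). WT and KO are red and the 7 lines expressing an HSF1 form are blue. For g238 the means were 2555 in WT, 0.286 in KO and 0.308 in V4, against 3249 in V1.

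After 48 h in trehalose the same comparison asked what HSF1 contributed during the treatment that precedes drying. The transcript g6912 fell from 97.4 ± 5.48 CPM in WT to 0.393 ± 0.180 in KO (log2 -7.93, SE 0.24). The transcript g240, at 11.2 ± 4.01 CPM in WT, had 0 counts in KO and was at least 50.6-fold lower. In the other direction, g11936 rose from 1.96 ± 0.321 CPM in WT to 317 ± 7.58 in KO (log2 7.30, SE 0.14). The transcript g10534 had 0 counts in WT and 7.81 ± 2.63 CPM in KO, at least 30.1-fold higher. The edgeR adjusted p values were 2.96e-59 for g6912, 2.33e-19 for g240, 1.06e-79 for g11936 and 5.62e-13 for g10534. The libraries of both groups did not overlap for any of these 4 genes, as the rule for named genes required. Over 8255 genes, 2345 differed, 1103 higher and 1242 lower in KO. Among differences of at least 2-fold, 411 genes were lower and 162 higher.

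Many genes affected by the KO were affected in the same direction in both treatments. Of 7826 genes tested at both, 427 were higher in KO at both T48 and HS6h, where 146 would be shared by independent lists of the same sizes. Another 484 were lower in KO at both, against 180 for independent lists, and 166 went in opposite directions, against 324. The log2 differences of the 2 treatments had a Pearson correlation of 0.553 across genes, which are not independent replicates. A direct test of the difference between the KO effects at T48 and HS6h called 1359 genes. In 687 of them the effect, signed as KO over WT, was higher at T48 and in 672 it was higher at HS6h. The transcript g14583 was among them: after heat shock it had 13.5 ± 2.90 CPM in WT and 2 counts in all in KO, a ratio of 92.2 with an exact Poisson interval of 25.5 to 761, while at T48 WT had 1.78 ± 0.757 CPM and KO 1.19 ± 0.808 CPM. Its difference of effects was 5.80 on the log2 scale (SE 1.13, edgeR adjusted p 4.28e-05).

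A minority of heat-induced genes was lower in KO than in WT after heat shock. Of all 2607 heat-induced genes tested in both fits, 491 were lower in KO, where independent lists would share 391. Another 466 were higher, also a larger share than the 1087 higher among all 8264 genes tested at HS6h. The excess was therefore not confined to genes lower in KO. In WT, 293 of these genes were at least 4-fold higher at HS6h than at T48. Of them, 85 were lower in KO than in WT after heat shock, where independent lists would share 44, and 40 were higher. Simulated unchanged KO groups shared 0 genes in 20 runs, but they were drawn at the means of the same WT libraries. These runs therefore cannot measure what sharing those libraries adds. The heat-induced list and the KO list both use the WT heat shock libraries, which are too few to split. Part of either excess of lower genes may come from sharing them. The other 208 were not lower in KO. A direct test of the response, HS6h over T48, called it smaller in KO than in WT for 25 of the 293 genes and larger for 14. The median response of the 85 genes, as log2 of HS6h over T48, was 2.74 ± 0.08 in WT and 1.18 ± 0.16 in KO (SD over 3 heat shock libraries). The median response of the 208 genes was 2.15 ± 0.02 in WT and 2.28 ± 0.07 in KO. The 85 genes were picked by their KO level, so the size of their loss in KO is partly set by that choice, while the 7 other lines were not used in it.

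**Figure D2:**
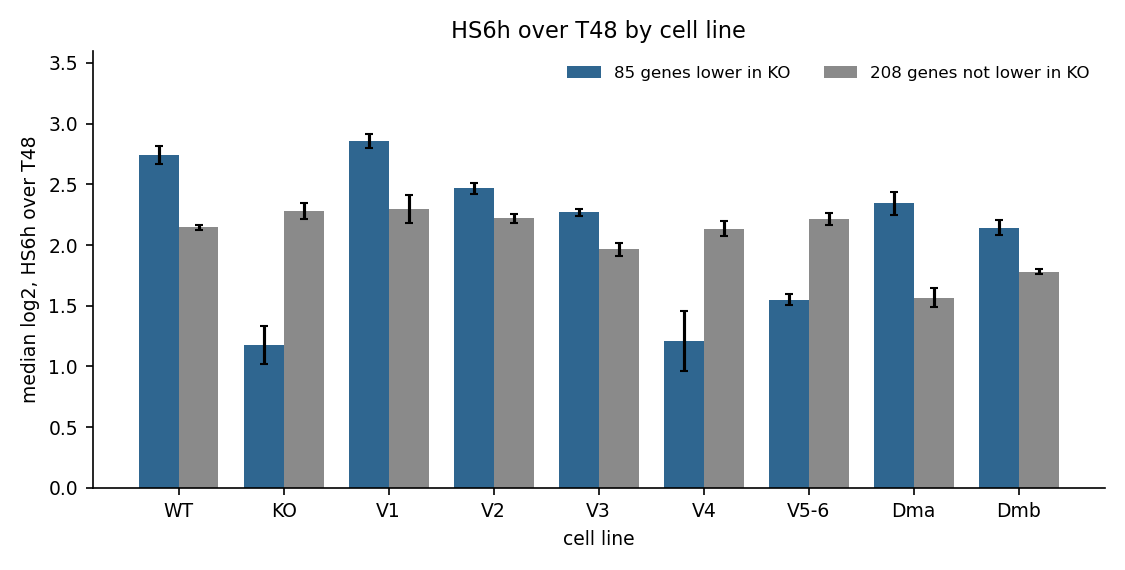
Median log2 response, HS6h over T48, of 85 heat-induced genes that were lower in KO than in WT at HS6h (blue) and of the 208 that were not (grey), by cell line. Bars are means over the 3 heat shock libraries and error bars are their SD. The blue bar is 1.21 in V4 and 1.55 in V5-6, against 2.74 in WT, while the grey bars of these lines lie at 2.13 and 2.22.

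Whether each HSF1 form could stand in for the missing gene was asked by comparing each line with KO. After heat shock V1, V2, V3 and Dma returned the transcripts g238 and g241 to the WT level or somewhat above it, and Dmb brought them back in part. V5-6 raised both above KO but left them far below WT, and V4 left both at the KO level. The transcript g238 reached 3249 ± 268 CPM in V1, 2616 ± 27.5 in V2, 3240.1 ± 47.1 in V3, 2997 ± 346 in Dma and 1080.2 ± 319 in Dmb, against 9.25 ± 1.47 in V5-6 and 0.308 ± 0.271 in V4. The transcript g241 reached 1647 ± 128 CPM in V1, 1347 ± 60.8 in V2, 1572 ± 6.29 in V3, 1528 ± 96.5 in Dma and 529.8 ± 151 in Dmb. In V5-6 it had 4.35 ± 2.10 CPM, a ratio to KO of 61.1 with an exact Poisson interval of 11.0 to 2413, and V4 held 1 count, as KO did. For g238 the log2 difference from KO was 13.35 (SE 0.33) in V1, 13.00 (SE 0.33) in V2, 13.32 (SE 0.33) in V3, 13.20 (SE 0.33) in Dma and 11.75 (SE 0.35) in Dmb, with edgeR adjusted p values of 1.24e-16 or less. The largest rises in V4 were in other genes, g4155 at 243.7 ± 11.8 CPM against 9.55 ± 2.23 in KO (log2 4.68, SE 0.11) and g14965 at 125 ± 9.80 CPM against 6.97 ± 0.858 (log2 4.21, SE 0.14).

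Over the 353 genes that were at least 2-fold lower in KO after heat shock, V4 and V5-6 were again the lowest of the lines, though above KO. Their mean log2 difference from WT was -1.85 ± 0.04 in KO (SD, n = 3). It was 0.08 ± 0.04 in V1, -0.25 ± 0.02 in V2, 0.13 ± 0.02 in V3, -0.01 ± 0.05 in Dma and -0.24 ± 0.05 in Dmb. In V4 it stayed at -1.24 ± 0.00 and in V5-6 at -0.998 ± 0.019. Against KO, 166 of the genes were called higher and 18 lower in V4, and 170 higher and 4 lower in V5-6. The genes were picked by their level in these same KO libraries, so part of the distance above KO may come from that choice. In the set chosen at T48, given below, V4 lay close to KO. The fry test of limma put the set lower in V4 than in V1, V2 and V3, with adjusted p values over 160 set tests of 1.64e-21, 3.17e-19 and 8.18e-22. For V5-6 against the same 3 lines they were 7.75e-20, 1.16e-16 and 2.37e-20. Of the 353 genes, 154 were called lower in V4 than in each of V1, V2 and V3, and 26 higher than in each of them. In V5-6 124 were called lower and 6 higher than in each of the 3. The 411 genes at least 2-fold lower in KO at T48 were chosen in other libraries and again put V4 and V5-6 lowest of the lines after heat shock, with mean differences from WT of -0.80 ± 0.02 in KO, -0.73 ± 0.02 in V4 and -0.36 ± 0.01 in V5-6. The other 5 lines lay between -0.09 ± 0.02 (Dmb) and 0.34 ± 0.03 (V3) for that set.

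**Figure D3:**
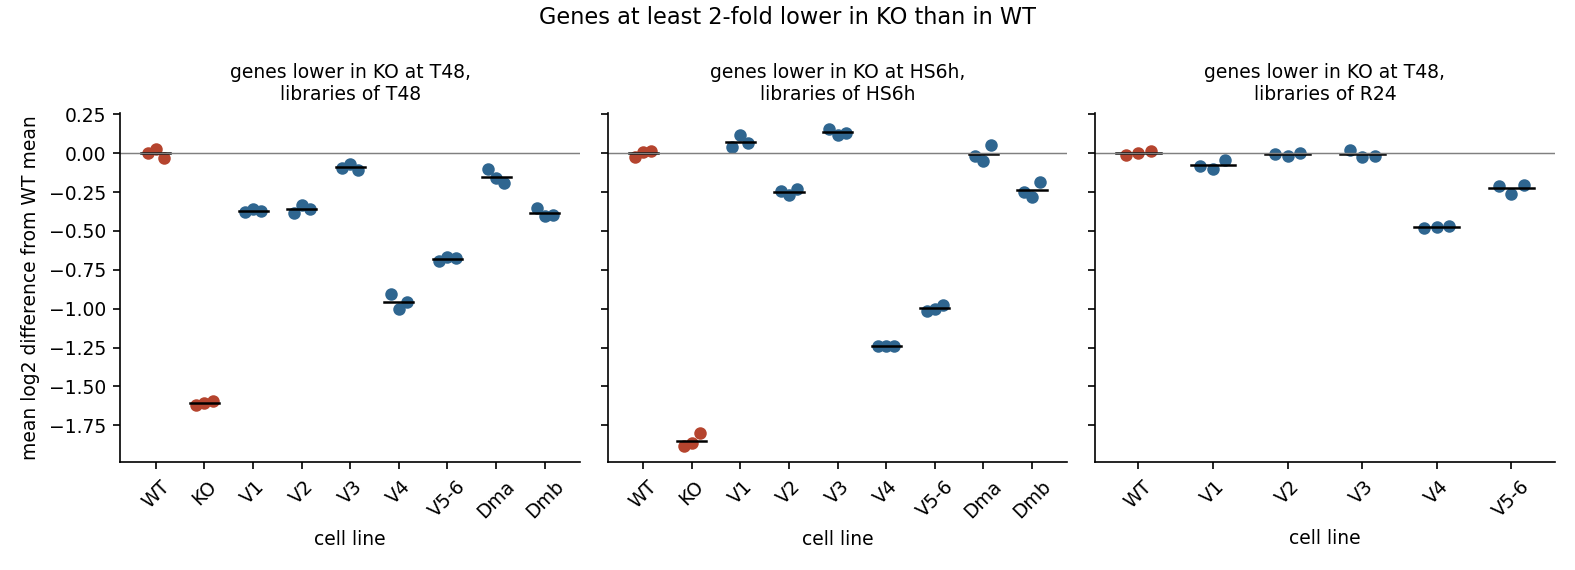
Mean log2 difference from the WT mean of genes at least 2-fold lower in KO than in WT, for each library (points) and cell line (lines). The left panel scores 411 genes at T48, the middle panel 353 genes at HS6h and the right panel the 411 genes of T48 in the R24 libraries. WT and KO are red, and V4 and V5-6 lie below V1, V2 and V3 in each panel.

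The 208 heat-induced genes not lower in KO had a median above 0 for HS6h over T48 in every line. In the 85 heat-induced genes that were lower in KO, the median response was 2.86 ± 0.06 in V1, 2.47 ± 0.04 in V2, 2.27 ± 0.03 in V3, 2.34 ± 0.09 in Dma and 2.14 ± 0.06 in Dmb, but 1.21 ± 0.25 in V4 and 1.55 ± 0.05 in V5-6. In the 208 other heat-induced genes it was 2.13 ± 0.06 in V4 and 2.22 ± 0.05 in V5-6, near the 2.15 ± 0.02 of WT. The Drosophila lines had the lowest medians for these genes, 1.57 ± 0.08 in Dma and 1.78 ± 0.02 in Dmb.

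Counted over all genes, a large part of the KO-affected genes was called back toward WT in each line, and some of these past it. The calls do not say whether the HSF1 form or the clone brought this about. Of the 2328 genes that differed between KO and WT after heat shock, 75.1% were called back toward WT in Dma and 75.3% in Dmb. The Pv isoforms followed with 67.7% in V3, 64.9% in V4, 58.1% in V1, 45.1% in V5-6 and 41.6% in V2. Some of these genes were called on the other side of WT: 856 in Dmb, 638 in Dma, 548 in V3, 325 in V1, 269 in V4, 204 in V2 and 85 in V5-6. Without them the order was different, with 53.4% in V4, 47.7% in Dma, 44.1% in V3, 44.1% in V1, 41.5% in V5-6, 38.6% in Dmb and 32.8% in V2. Fewer of the strongly reduced genes were called back in V4. Of the 353 genes at least 2-fold lower in KO, 47.0% were called back in V4, against 76.5% in V1, 61.8% in V2, 76.8% in V3, 80.2% in Dma, 76.2% in Dmb and 48.2% in V5-6. Of the 1087 genes higher in KO, 72.2% were called back in V4. These counts share the KO libraries with the list of KO-affected genes, and part of any excess over independent lists may come from that. In 20 simulations of unchanged lines no gene was called back. These lines were drawn at the means of the same KO libraries, so the runs cannot measure what sharing adds. Independent lists would give between 253 (V5-6) and 594 (Dmb) of the 2328. The numbers of genes called between each line and KO were 2731 for V1, 2280 for V2, 3473 for V3, 3001 for V4, 1790 for V5-6, 3810 for Dma and 4209 for Dmb.

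**Figure D4:**
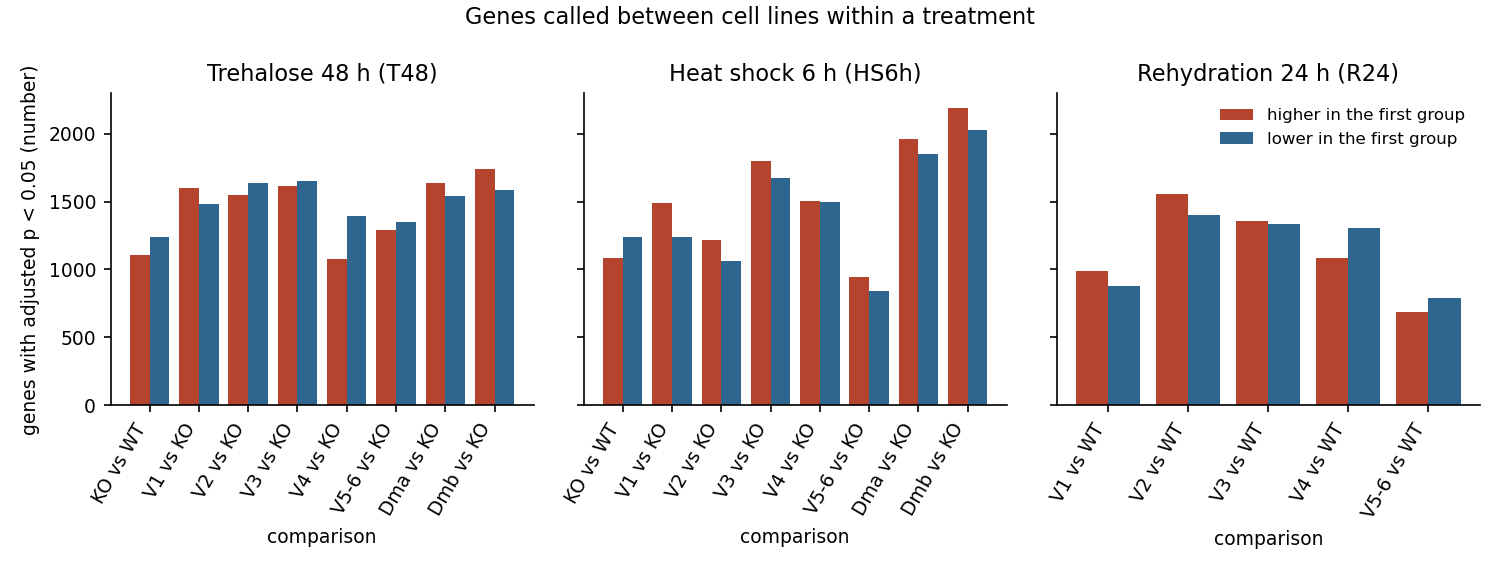
Number of genes with an edgeR adjusted p under 0.05 in comparisons between cell lines within a treatment, split into genes higher (red) and lower (blue) in the group named first. The counts for Dmb against KO after heat shock, 2186 higher and 2023 lower, are the largest shown.

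At T48 the transcript g6912 returned in V1, V2 and V3, in part in V5-6, Dma and Dmb, and hardly in V4. This transcript, at 97.4 ± 5.48 CPM in WT and 0.393 ± 0.180 in KO, rose to 219.6 ± 14.6 CPM in V1, 263 ± 9.79 in V2, 196 ± 12.6 in V3 and 60.4 ± 5.45 in V5-6. It had 28.3 ± 4.58 CPM in Dma, 49.0 ± 4.77 in Dmb and 5.28 ± 2.56 in V4. In V1, V2 and V5-6 its log2 difference from KO was 9.13 (SE 0.21), 9.36 (SE 0.21) and 7.23 (SE 0.26), with edgeR adjusted p values of 1.21e-71, 2.77e-74 and 1.58e-51. The transcript g240, with 0 counts in KO, was at least 50.9-fold higher in V1, at least 67.3-fold higher in V2 and at least 137-fold higher in V3. In Dma it reached 80.3 ± 7.06 CPM, at least 361-fold above KO and above the 11.2 ± 4.01 CPM of WT. The largest rises in V4 were g10530, at 82.7 ± 11.9 CPM against 0.650 ± 0.823 in KO, and g14965, at 117 ± 5.93 CPM against 3.01 ± 0.375. The largest falls at T48 included g5365, which had 6.58 ± 2.02 CPM in KO and 0 counts in V1, V2 and V3, at least 33.6-fold, 29.4-fold and 32.1-fold lower.

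The set of 411 genes at least 2-fold lower in KO at T48 had a mean log2 difference from WT of -1.61 ± 0.02 in KO, -0.96 ± 0.05 in V4 and -0.68 ± 0.02 in V5-6. It lay at -0.37 ± 0.01 in V1, -0.36 ± 0.03 in V2, -0.09 ± 0.02 in V3, -0.15 ± 0.05 in Dma and -0.39 ± 0.03 in Dmb. V4 was lower than V1, V2 and V3 over this set (limma's fry, adjusted p 8.62e-20, 7.26e-20 and 5.49e-22), and so was V5-6 (8.68e-15, 1.55e-14 and 1.78e-18). Of the 2345 KO-affected genes at T48, 67.1% were called back toward WT in V3, 63.2% in V1, 60.3% in Dma, 60.3% in Dmb, 48.5% in V2, 48.4% in V5-6 and 44.7% in V4. Of these genes, between 208 (V4) and 434 (V2) per line were called on the other side of WT. Without them the shares were 49.9% in V3, 46.7% in V1, 44.3% in Dma, 43.2% in Dmb, 37.5% in V5-6, 35.9% in V4 and 30.0% in V2. Simulated unchanged lines, drawn at the KO means, gave 0 in each of 20 runs, which again cannot measure the effect of shared KO libraries. Independent lists would give between 349 (V4) and 474 (Dmb) genes. The lines differed from KO by 3086 (V1), 3185 (V2), 3267 (V3), 2472 (V4), 2641 (V5-6), 3175 (Dma) and 3331 (Dmb) genes.

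Return toward WT was not complete in any line. At T48 272 of the KO-affected genes were called back in all 7 lines and 167 in none, and at HS6h 363 were called back in all 7 and 100 in none. Of those called back in none, 59 at T48 and 28 at HS6h differed from WT in all 7 lines. The transcript g11936 stayed far above WT in every line: after heat shock it lay between 29.6 ± 6.95 CPM (Dmb) and 186 ± 7.26 CPM (V3), where KO had 100.7 ± 6.10 and WT 0.247 ± 0.214. Dma, at 60.4 ± 4.56, and Dmb were below KO, and V3 was above it. Each line also differed from WT, by a median of 2387 genes over 14 comparisons. The labels describe clonal cell lines and give 1 line per HSF1 form, so effects of the form and of the clone are read together in every comparison between lines.

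The 5 Pv isoforms differed widely among themselves. A test for any difference among them called 4812 genes at T48, 4976 at R24 and 4958 at HS6h. Among the smallest p values at both T48 and HS6h was g11500: at T48 it had 1013 ± 23.4 CPM in V2 and 116.5 ± 13.2 to 232 ± 7.84 in the 4 other isoform lines, and after heat shock 4328 ± 51.4 in V2 against 285 ± 9.53 in V1. The transcript g4155 had 1727 ± 72.7 CPM in V4 and 88.1 ± 6.00 in V2 at T48, and 409 ± 34.6 against 16.5 ± 0.384 at R24. The transcript g2540 had 2248 ± 32.6 CPM in V2 and 55.4 ± 10.1 in V1 at T48. The edgeR adjusted p of the tests over isoforms was 1.26e-82 for g11500, 4.19e-92 for g4155 and 4.85e-75 for g2540 at T48. Pairs of isoforms differed by a median of 2103 genes over 30 comparisons, from 652 (V3 against V2 at R24) to 4266 (V4 against V2 at R24).

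The Drosophila forms were compared with each other in the same background. The largest rise by the fixed rule at both treatments was g3835, which had 216 ± 4.90 CPM in Dmb and 0 counts in Dma at T48, at least 722-fold higher. After heat shock it had 73.3 ± 3.98 CPM in Dmb and 1 count in all in Dma, a ratio of 1136 with an exact Poisson interval of 204 to 44862. In the other direction, g14437 had 1.13 ± 0.492 CPM in Dmb and 48.7 ± 13.0 in Dma after heat shock (log2 -5.37, SE 0.34, edgeR adjusted p 1.38e-25). In all, 1696 genes differed at T48 (959 higher and 737 lower in Dmb) and 2034 at HS6h (989 higher and 1045 lower). The genes at least 2-fold lower in KO were somewhat lower in Dmb than in Dma. Their median log2 was -0.16 over the 411 genes at T48 and -0.14 over the 353 genes at HS6h (limma's fry, adjusted p 6.82e-08 and 1.02e-06).

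After desiccation and 24 h of rehydration the isoform lines could be compared only with WT, since no KO library is among those of R24. The transcript g11941 had 0 counts in WT and was higher in all 5 lines, from 8.48 ± 1.09 CPM in V1 (at least 59.1-fold) to 19.9 ± 3.35 in V4 (at least 141-fold). The transcript g10533, also at 0 counts in WT, had 8.61 ± 2.19 CPM in V2, 10.8 ± 1.85 in V3, 9.20 ± 1.81 in V4 and 12.0 ± 1.35 in V5-6. The transcript g8837 had 5.06 ± 2.16 CPM in WT and 0 counts in V1, V2, V3 and V5-6, at least 42.8-fold lower in V1, with 1 count in V4. Its absence was not particular to R24. KO also had 0 CPM at T48, where WT had 3.49 ± 0.379, and at HS6h, where WT had 1.83 ± 0.453. V4 stood apart with g239, at 0.888 ± 0.153 CPM against 83.9 ± 6.99 in WT (log2 -6.53, SE 0.36, edgeR adjusted p 5.30e-09), where V5-6 had 10.7 ± 1.56 CPM and V1, V2 and V3 had 97.6 ± 23.2 or more. The set of 411 genes at least 2-fold lower in KO at T48 had a mean log2 difference from WT of -0.47 ± 0.00 in V4 and -0.23 ± 0.03 in V5-6 at R24. It lay at -0.08 ± 0.03 in V1, -0.01 ± 0.01 in V2 and -0.01 ± 0.03 in V3. Over the 400 members tested at R24, V4 was lower than V1, V2 and V3 (limma's fry, adjusted p 8.81e-12, 1.11e-12 and 1.97e-12), as was V5-6 (2.65e-06, 2.72e-08 and 4.67e-08). Single libraries stood apart at this treatment. In V1, V2 and V4 the pairs with replicate 2 had variances of 9.72 to 15.3 times counting error and the remaining pairs 3.20 to 3.62, and in V3 replicates 1 and 3 gave 11.3. Against WT, 1874 genes differed in V1, 2960 in V2, 2694 in V3, 2394 in V4 and 1476 in V5-6.

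WT cells differed strongly between treatments. After heat shock g17056 had 118 ± 7.73 CPM and at T48 0 counts, at least 437-fold higher, and g17055 rose from 0.522 ± 0.516 to 1856 ± 110 CPM (log2 11.69, SE 0.28). The transcript g12762 went the other way, from 90.6 ± 5.09 CPM at T48 to 0.246 ± 0.113 after heat shock (log2 -8.41, SE 0.25). At R24 g10714 had 405 ± 19.3 CPM against 0.625 ± 1.08 at T48 (log2 9.28, SE 0.31), and g3255 fell to 4.65 ± 0.538 from 130 ± 12.5 CPM (log2 -4.80, SE 0.17). The edgeR adjusted p values were 1.18e-31 for g17055, 3.91e-55 for g12762, 2.97e-32 for g10714 and 2.24e-49 for g3255. Over all genes, 5264 differed between HS6h and T48, 2626 higher and 2638 lower, and 4887 differed between R24 and T48, 2451 higher and 2436 lower. The labels do not say whether the treatments were run side by side, so a batch between treatments and the treatment are read together here.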

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

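The count of genes with opposite KO effects and the splits of the libraries were chosen after the results were seen, while the test of the difference itself was planned before the data were examined. The effect of the KO differed between trehalose and heat shock: a test of the difference called 1359 genes with edgeR at an adjusted p under 0.05. For 166 genes KO and WT differed significantly at both treatments and in opposite directions, and all 166 were called in the test of the difference. Of these, 87 were higher in KO at T48 and lower in KO at HS6h, and 79 were the reverse. Independent lists of the same sizes would give 324 genes in opposite directions, so opposite effects were fewer, and genes changed alike were more, than for unrelated lists.

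The genes with the largest differences of effect had few counts, and 2 of the 4 named by the fixed rule lost their call when a library was left out. The transcript g17042 had an adjusted p of 0.408 without replicate 3 of KO at T48, and g12707 had 0.0663 without replicate 2 of WT at T48. In a fit of only the 12 libraries concerned the test called 1512 genes, more than any other of 100 splits of these libraries, of which the highest called 544. Every other split mixed KO with WT libraries at T48, HS6h or both, which lowers the count wherever these genotypes differ. The splits therefore cannot decide whether chance contributed to the count. No technical or biological explanation of the difference was tested.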

How the results depend on the processing

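The sum over transcripts and the removal of near-identical genes were chosen after the data were seen, and the other alternatives were planned. Over 45 counts of genes (the comparisons, the recovery counts and 2 medians over families), each stayed within 1.5 times its main value with RLE size factors, DESeq2, no filter on low counts, fits of only the groups compared, the sum over all transcripts and near-identical genes kept once. Leaving out each library in turn gave 426 values, between 0.741 and 1.11 times the main count, the lowest and highest both for V4 against WT at R24 (1773 and 2655 against 2394).

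Only the added threshold of 2-fold moved the counts by more, and it moved all 45, because it keeps a subset of the same calls. At T48 it left 573 genes for KO against WT, and against KO 860 for V1, 951 for V2, 881 for V3, 472 for V4, 598 for V5-6, 953 for Dma and 947 for Dmb. It left 309 for Dmb against Dma and 1526 for differences among the isoforms. At HS6h it left 564 for KO against WT, and against KO 809 for V1, 641 for V2, 1145 for V3, 690 for V4, 343 for V5-6, 1233 for Dma and 1576 for Dmb. It left 376 for Dmb against Dma and 1358 among the isoforms. At R24 it left 521 for V1, 723 for V2, 691 for V3, 565 for V4 and 381 for V5-6 against WT, and 1253 among the isoforms. The difference of KO effects kept 430, WT at R24 against T48 2106 and WT at HS6h against T48 2518. Genes back toward WT by at least 2-fold numbered 462 in V1, 419 in V2, 474 in V3, 216 in V4, 320 in V5-6, 489 in Dma and 496 in Dmb at T48. At HS6h they numbered 458 in V1, 339 in V2, 610 in V3, 381 in V4, 197 in V5-6, 669 in Dma and 828 in Dmb. The median over lines against WT was 560 and over pairs of isoforms 465.

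Of 1524 values of the 116 named results under these alternatives, none changed direction and 3 lost their call: g17042 and g12707, described above, and g12682 in Dmb against Dma at HS6h under DESeq2 (adjusted p 0.479). The cause was not tested. RLE size factors moved the share of higher calls by at most 4.27 points. No paired analysis was possible because the labels number the libraries 1 to 72 and give no replicate number shared between groups. Depth limited genes near 3 counts per group: folds against 0 counts are bounds, and ratios to 1 to 3 counts have wide Poisson intervals.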

Other observations

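All tests below were chosen after the results were seen. For every comparison of 3 libraries against 3 the real split called the most genes, 1 of 10 splits, which are too few for a share under 0.05. KO against WT called 2345 and 2328 genes and the highest other split 0. The 14 comparisons of a line with KO called 1790 to 4209 (highest other 3), and the 14 of a line with WT at T48 and HS6h called 1562 to 3241 (highest other 45). Dmb against Dma called 1696 and 2034 (highest other 97), isoforms against WT at R24 1476 to 2960 (highest other 0), WT between treatments 4887 and 5264 (highest other 1), and pairs of isoforms 652 to 4266 (highest other 3). For differences among the 5 isoforms, 1 of 100 splits, the real one, gave as many genes in each treatment (4812, 4976 and 4958, with 2375, 1916 and 2266 the highest others). The other splits mix libraries of different lines within a group. They show that libraries of a line were more alike than mixed ones, and cannot separate the isoform from the clone or the culture.

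As a set, the 353 genes at least 2-fold lower in KO after heat shock were lower in V4 and V5-6 than in V1, V2 and V3. Of them, 166 and 170 were called above KO, in part perhaps because the set was picked by the same KO libraries. Scaling, which moves all genes of a library alike, is argued against for V4, where the set median against that of all other genes was -0.564 (log2) or lower in each comparison. For V5-6 this difference was -0.697 against V1, -0.493 against V2 and -0.855 against V3. The value against V2 missed the bound of -0.5 set for the test. Yet the other genes had medians between -0.004 and 0.013 in these comparisons. Scaling would move the set and the other genes alike, so these values argue against it as the whole cause for V5-6 too. Fewer reads at g3611 are argued against as the whole cause at HS6h, since the lower of the V4 and V5-6 means was 1.27 times the lowest mean of V1, V2 and V3. V5-6, at 905 ± 14.0 CPM, was still below V1, at 1031 ± 118. At T48 the means of V4 and V5-6 were below those of V1 and V3 and above that of V2. Whether these reads follow the introduced transcript is open, as weighed next. A heat shock that did not reach these lines stays open: the 208 heat-induced genes not lower in KO were higher at HS6h than at T48 by 2.13 (log2) in V4, but without untreated cells heat is not separated from trehalose or batch. Differences between clones cannot be told apart from the isoform, because the labels give 1 line per isoform, and V4 and V5-6 may differ from the others in either way.

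The transcript g3611, chosen after its values were seen, was higher in all 5 Pv isoform lines and not in the Drosophila lines. After heat shock it had 712 ± 27.0 to 1065 ± 36.4 CPM in the Pv isoform lines, against 173 ± 8.12 in WT, 264 ± 34.8 in KO, 258 ± 49.4 in Dma and 149.7 ± 12.3 in Dmb (SD, n = 3). Transcription of neighbouring numbers was argued against as the whole cause: against KO, g3610 lay between -1.02 and -0.01 (log2), g3612 between -1.63 and 0.49 and g3611 between 0.55 and 2.04, and g3611 exceeded both by 0.77 or more in each comparison. That reads of the introduced isoforms were counted at g3611 stays open: the ratio of its models t20 and t1 was lower in each V4 library than in each library of other lines in 3 of 3 treatments, but V4 had 0.0533 ± 0.00750 at HS6h (KO 0.447 ± 0.0549), 0.415 ± 0.00337 at T48 (KO 0.571 ± 0.00105) and 0.404 ± 0.0510 at R24 (WT 0.511 ± 0.00529). A single added transcript would give V4 a ratio near that of HS6h at R24, where g3611 had 3563 ± 867 CPM against 159 ± 10.7 in WT, unless the cells' own g3611 rose too, which also stays open.

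A run of 50 tested genes with numbers from g12497 to g12618, found among 156 such runs at T48, was lower than WT in KO and in all 7 lines. It was picked for this: the rule asked for T48 medians on the same side of WT in KO and all 7 lines. Among such runs it took that whose smallest median was furthest from 0. Its median log2 difference from WT was between -0.61 and -0.17 at HS6h and, in the 5 lines measured there, between -0.29 and -0.20 at R24, and 6 of the 156 runs, this one and the next one included, had all 13 medians of these treatments below 0. In V1, V2 and V3, with HSF1 forms, the medians were -0.172 or lower, at HS6h and R24 too. A run that returned to WT in these lines could not have been picked. These medians therefore cannot decide whether the lack of HSF1 contributed. A few strongly changed genes hardly move a median, so the choice by medians had already set that explanation aside and it was not tested. At HS6h and R24 80.6% of the values of genes and lines were below 0, against 71.1% for a neighbouring run and 50.5% for the median run. Near-identical genes are argued against, since the run has 0 of them. A change in the founder of the KO cells, such as a lost copy of this stretch, or its opposite in the WT cells may explain the run, but DNA was not measured here, and WT libraries are shared by all comparisons within a treatment.

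Some genes set the 7 lines apart from both WT and KO. At T48 30 genes were higher than in WT and in KO in all 7 lines and 22 were lower, and at HS6h 14 and 16. Of these, 5 were higher and 9 lower at both treatments, where independent lists would share 0.0537 and 0.0450 genes. The transcript g10530, named in V4 by the fixed rule, had 41.0 ± 5.04 to 82.7 ± 11.9 CPM in the lines at T48, against 0.650 ± 0.823 in KO and 0.188 ± 0.326 in WT. The transcript g5568 had 0.512 ± 0.162 to 5.42 ± 0.912 CPM in the lines after heat shock, against 57.4 ± 5.17 in KO and 24.2 ± 5.74 in WT.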
